A study of Mus musculus with 7 samples.

How the data were processed

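Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was applied to small numbers of mouse cells. The labels list 7 samples: 3 of H3K4me3, 2 of H3K27me3 and 2 of H3K36me3. LSK cells are bone marrow cells sorted for absence of lineage markers and presence of Sca and Kit, a fraction that holds hematopoietic stem cells and early progenitors. Only replicate 2 of H3K27me3 and replicate 2 of H3K36me3, both from LSK cells, were analysed here, and the other 5 samples were not analysed here.

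Per the labels' protocols, picogram amounts of immunoprecipitated DNA were copied with a primer that ends in a random 9-mer and carries a BciVI restriction site. The copies were then amplified by PCR and cut with the enzyme before sequencing. The deposited values are read sequences of 36 bases with a Phred quality for each base, that is, unaligned reads before any counting. The submitters' processing notes name the mouse build mm8, and the aligner is not given in the sources used here.

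The analysis fixed before the data were examined covered promoters, gene bodies and 14 gene lists, for which reads must be placed on a genome. A genome sequence was not used here, so none of those results was made, and the rule for naming genes had nothing to act on. What remained of that plan is the description of each library from its sequences. The other results below, with all of their alternatives, were chosen after the files were seen to hold reads. No build or coordinate therefore stands behind any value.

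Reads were kept where they had no unread base (N), did not hold the amplification primer and did not match any of 4 fixed sequences found in both libraries. Peptides and base composition were counted over distinct reads, that is, 1 read per identical 36-base sequence. Repeats were counted over all kept reads, because identical reads from repeats can come from different copies. Protein families were counted by translating each read in 6 frames and searching for short peptides that are conserved within a family. A first panel of 38 families was written before any peptide was counted. Its counts were small, and a second panel of 40 families with shorter and additional peptides was written after those counts had been seen. The second panel gives the values of the report, and the first stands beside it where the groups are compared. The level expected by chance was measured with 20 shuffled forms of each peptide, and a family was called above chance where the lower bound of the 95% Poisson interval of its reads in both libraries together exceeded that level. Peptides, repeat sequences and the mitochondrial COX1 protein were written from general knowledge and checked against the reads.

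Reads of a repeat were those holding a word of 21 bases from its consensus, on either strand. A consensus for 18S ribosomal DNA was left out of the results because none of its words reached 50 reads in either library. Mitochondrial reads were found by words of 9 residues from COX1 in the mitochondrial code. A pair of broader searches was added after these counts: encoded hexapeptides with at least 5 different residues, and all words of 21 bases with at least 200 reads in a library.

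Shares of reads were compared as the log2 ratio of H3K27me3 over H3K36me3, with exact (Clopper-Pearson) 95% bounds conditional on the total. Shares of a single library carry Wilson intervals. Ratios stratified by the number of G and C bases of the read used the Mantel-Haenszel estimate with Robins-Greenland bounds. For repeats and COX1 this estimate set the reads against all other reads, so it is not a ratio of shares like the main value. PCR reads without molecular identifiers are not independent molecules, so intervals cover counting error only. With 1 library per mark, no difference has a replicate check, and each interval compares these libraries, not the marks. No input or control library is among the samples. A ratio therefore cannot tell enrichment in 1 library from depletion in the other.

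The search, the repeat words and the intervals were tested on simulated data. Of the simulated reads with a planted peptide from the 40 families of the second panel, 100% were found, as were 100% of those with a planted stretch of the 9 repeats. The planted sequences were those searched for, so this checks the search and not the sequences themselves. The 9 repeats include the ribosomal consensus that was left out of the results. How many diverged copies or reads with errors are missed was not tested. At 5 true ratios with 2000 draws each, between 95.35% and 96.65% of exact intervals and between 94.7% and 95.35% of stratified intervals held the true ratio. The draws were independent Poisson counts of more reads than many single families gave. Coverage at few reads, or with PCR copies, was not tested. Alternatives changed the treatment of identical reads, GC content, chance matches, read quality, read part, depth and scaling. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Numba 0.67.0, and figures were drawn with Matplotlib 3.10.9.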

Results

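H3K27me3, the mark laid down by Polycomb repressive complexes at silent genes, and H3K36me3, the mark that accompanies transcription through gene bodies, were profiled in LSK cells, the stem and progenitor fraction of mouse bone marrow. Each mark was represented by 1 library, replicate 2 of its group. The H3K27me3 library held 32785645 reads of 36 bases and the H3K36me3 library 32215410. After removal of reads with unread bases, primer or fixed sequences, 28175625 and 25199546 reads were kept, of which 23061852 and 20878129 were distinct sequences. Identical copies made up 18.1% of kept reads for H3K27me3 and 17.1% for H3K36me3. The GC content of kept reads was 42.2% and 41.6%. The H3K36me3 lane had more unread bases: 82.0% of its reads were free of them, against 90.3% for H3K27me3.

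The comparison asks which kinds of genes and sequences each library is richer in relative to the other. Since reads were not placed on a genome, genes were read out as protein families, through reads that encode a peptide conserved in the family. Of the 4 groups compared, the widest contrast was in KRAB and other C2H2 zinc finger genes, a large class of transcription factors of which many silence retroelements. Reads encoding their peptides were 8.41-fold more frequent in the H3K36me3 library, with 1188 distinct reads against 156 in H3K27me3 (log2 ratio H3K27me3 over H3K36me3 −3.07, 95% counting interval −3.32 to −2.83). The linker between C2H2 zinc fingers, TGEKPY or TGEKPF, accounted for 1028 and 114 of these reads, a log2 ratio of −3.32 (interval −3.61 to −3.04). The KRAB domain, the repression module of the KRAB members of this class, was found in 160 H3K36me3 reads and 42 H3K27me3 reads. Shuffled peptides gave 13.4 and 16.9. Its log2 ratio was −2.07 (interval −2.60 to −1.57), and −2.69 with chance matches subtracted. A single spelling held 13 of the 42 H3K27me3 reads and 7 of the 160 in H3K36me3, and without it the log2 ratio was −2.54 (interval −3.17 to −1.96). The linker reads came in 180 different DNA spellings in H3K36me3 and 47 in H3K27me3, and the most frequent spelling held 20.04% and 23.7% of the reads.

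Families of broadly expressed machinery were likewise richer in H3K36me3. As a group of 11 families they gave 82 reads in H3K36me3 and 34 in H3K27me3, a log2 ratio of −1.41 (interval −2.04 to −0.82), while chance accounted for 14.9 and 18.4 of the reads. All 11 families were above chance over both libraries, and in 3 of them the interval lay wholly on the H3K36me3 side. These were the small GTPases, switches of membrane traffic and signalling, with 11 reads against 1, the AAA ATPases, motors of protein unfolding and complex disassembly, with 9 against 1, and the Ser/Thr kinases with 15 against 6. Of the kinase reads 3.25 and 3.6 were expected by chance, and with these subtracted their log2 ratio moved from −1.47 to −2.44. In bases 10 to 36 of the reads the log2 ratios were −2.47 (interval −8.03 to 0.69), −1.73 (−7.44 to 1.91) and −0.95 (−3.17 to 1.02), and all 3 intervals included 0, so these single families rest on few reads. DEAD-box RNA helicases, which remodel RNA in splicing and translation, gave 14 reads in H3K36me3 and 7 in H3K27me3. Of these, 5.15 and 6.25 were expected by chance. With these subtracted the log2 ratio moved from −1.14 to −3.70, but hardly any H3K27me3 reads remained, so −3.70 is not a measured fold. The interval without subtraction, −2.69 to 0.26, included 0. It also did so at equal GC content, with identical reads kept, with up to 2 N, at equal depth (−3.32 to 0.07) and in the start and the end of the file. It lay below 0 only in bases 10 to 36 (−4.61 to −0.25) and in reads with at least 30 good bases (−3.52 to −0.14). Tubulins gave 4 reads in each library. Another 4 families outside these classes (Tyr kinases, myosins, ETS domain and ankyrin repeats) leaned the same way. As a group they gave 7 reads in H3K36me3 and 1 in H3K27me3, with 0.5 expected by chance in each. Their log2 ratio was −2.95 (interval −8.44 to 0.01), so the lean was not shown to be particular to machinery.

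Families whose members are each expressed in few tissues or cell types leaned the other way. The tissue-restricted group of 6 families gave 246 reads in H3K27me3 and 95 in H3K36me3, a 2.34-fold difference (log2 ratio 1.23, interval 0.88 to 1.59). Chance accounted for 34.25 and 29 of the reads, and most of the reads came from olfactory receptors. Of the 5 families above chance, 2 had an interval wholly on the H3K27me3 side. Immunoglobulin heavy V segments, potassium channels and intermediate filaments gave at most 4 reads in a library. Olfactory receptors, the odorant receptors of the nasal epithelium, gave 160 reads against 51, with 18.4 and 16.8 expected by chance, for a log2 ratio of 1.51 (interval 1.04 to 1.99). Protocadherins and other cadherins, adhesion proteins with their greatest variety in neurons, gave 50 reads against 24, for a log2 ratio of 0.92 (interval 0.19 to 1.68). The ratio stayed at 0.69 in bases 10 to 36 (interval −0.31 to 1.75) and at 1.03 (−0.03 to 2.19) and 0.72 (−0.29 to 1.78) in the start and the end of the file, where all 3 intervals included 0. In H3K36me3, 7 of those 24 cadherin reads shared a single spelling that was absent from H3K27me3, and without it the log2 ratio was 1.41 (interval 0.59 to 2.30). Trypsin-type serine proteases gave 29 and 16 reads, of which 14.0 and 10.9 were expected by chance, and the interval of their log2 ratio of 0.71, −0.21 to 1.69, included 0. It was 1.09 (interval 0.03 to 2.25) in reads with at least 30 good bases, 1.41 with chance matches subtracted and 0.30 (interval −0.92 to 1.57) in bases 10 to 36.

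Developmental regulators did not separate the libraries as a group. Their 13 families gave 64 reads in H3K27me3 and 55 in H3K36me3, a log2 ratio of 0.08 (interval −0.47 to 0.62), with 20.6 and 18.9 reads expected by chance. Of the 13 families 7 were above chance, and 1 of these had an interval wholly on the H3K36me3 side. The counts cover only reads that encode the peptides. Promoters were not measured, so H3K27me3 at the promoters of these genes was not tested. Homeodomain proteins, the HOX type among them, gave 34 reads in H3K27me3 and 19 in H3K36me3 (log2 ratio 0.70, interval −0.15 to 1.59). That ratio was 1.19 (interval 0.15 to 2.34) in reads with at least 30 good bases, 1.27 with chance matches subtracted, and 1.15 and −0.32 in the start and the end of the file, where both intervals included 0. Forkhead proteins gave 3 and 13 reads, of which 2.3 and 2.05 were expected by chance. Subtraction of chance matches gave a log2 ratio of −4.11, but hardly any H3K27me3 reads remained, so −4.11 is not a measured fold. Without subtraction the log2 ratio was −2.26 (interval −4.71 to −0.40). The ratio was −1.94 in reads with at least 30 good bases (interval −4.44 to 0.01), −2.73 in bases 10 to 36 (−8.25 to 0.31), and −1.85 and −2.06 in the start and the end of the file, where all 4 intervals included 0, so the lean to H3K36me3 rests on few reads. The peptides of PAX proteins gave 8 reads in each library, and that of BMP ligands gave 0, so no difference was detectable there at this depth. Replication-dependent histones gave 0 reads in H3K27me3 and 3 in H3K36me3, with 1.25 and 0.9 expected by chance, and were not called above chance.

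**Figure D1:**
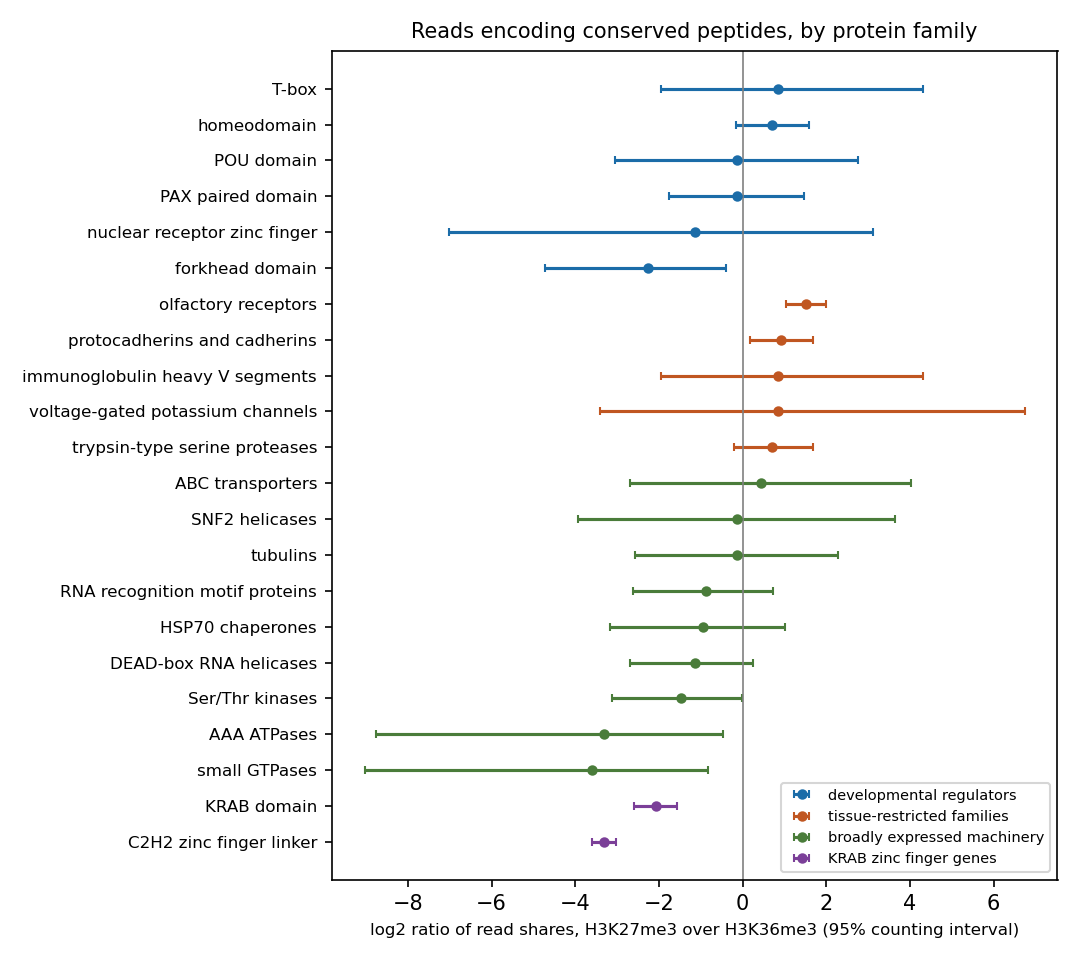
Log2 ratio of read shares, H3K27me3 over H3K36me3, for each protein family of 4 groups that was above chance and had reads in both libraries. Points are ratios over distinct reads of 1 library per mark and bars are 95% counting intervals; zinc finger families lie at −3.32 and −2.07 and olfactory receptors at 1.51.

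The first peptide panel was fixed before any peptide was counted. Its log2 ratios were −3.59 for KRAB and other C2H2 zinc finger genes, −2.81 for machinery, 1.50 for tissue-restricted families and −0.14 for developmental regulators. These came from 835, 22, 33 and 40 reads of both libraries. Of the developmental reads, the forkhead peptide gave 6 in H3K27me3 and 16 in H3K36me3. Chance gave 10.15 and 9.4, so it was not above chance, yet it weighs on the group's −0.14. Of the 6 developmental families above chance, 5 leaned to H3K27me3 and 1 to H3K36me3. Each had at most 4 reads in a library and an interval that included 0. Most of the zinc finger reads were of the C2H2 linker, with 750 in H3K36me3 and 70 in H3K27me3, against 15 and 0 of the KRAB box. No family ratio has a replicate check, and families of fewer than 10 reads constrain the ratio only loosely.

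Repeat sequences divided between the libraries as well. Major satellite, the AT-rich array of mouse pericentromeres, made up 12.01% of kept reads in H3K36me3 (95% Wilson interval 11.996 to 12.02) and 5.95% in H3K27me3 (interval 5.94 to 5.95). Its log2 ratio was −1.01, a 2.02-fold difference. Minor satellite, the centromeric array, was 1.92-fold higher in H3K36me3, with 0.224% of reads against 0.116%. Reads with an exact consensus word of the B1 and B2 SINEs, short retroelements frequent in gene-rich regions, were also more frequent in H3K36me3. The log2 ratios were −0.62 (interval −0.65 to −0.59) and −0.90 (interval −0.94 to −0.86). B1 reads made up 0.063% of H3K27me3 and 0.097% of H3K36me3 reads, and B2 reads 0.030% and 0.055%. SINE copies without such a word were not counted, so the ratios do not cover these families as a whole. The long terminal repeat of IAP retroviruses had a log2 ratio of −0.69 (interval −0.78 to −0.61), although only 35.9% and 55.0% of the words of its consensus were seen at 50 reads or more.

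Simple dinucleotide repeats were higher in H3K27me3. GA repeats made up 0.466% of its reads and 0.187% of H3K36me3 reads, a log2 ratio of 1.31 (interval 1.30 to 1.33). CA repeats made up 0.999% and 0.618%, a log2 ratio of 0.69 (interval 0.68 to 0.70). The L1 retroelement, read through its reverse transcriptase, gave 528 distinct reads in H3K27me3 and 372 in H3K36me3, a log2 ratio of 0.36 (interval 0.17 to 0.56). A single spelling held 698 of the L1 reads of both libraries, and without it the log2 ratio was 0.65 (interval 0.22 to 1.08). The interval of the first panel's longer L1 peptide, −0.003 to 0.51, included 0. Telomere repeats gave 3098 and 2810 reads and a log2 ratio of −0.02 (interval −0.09 to 0.05), and −0.11 (interval −0.19 to −0.02) with 1 read per identical sequence. The telomere ratio was −0.13 (interval −0.20 to −0.06) at equal GC content. With satellite reads left out of the totals it was −0.12 (interval −0.19 to −0.04). Mitochondrial COX1, which is outside chromatin, was higher in H3K27me3 with 284 reads against 144, a log2 ratio of 0.82 (interval 0.52 to 1.12), although only 47.2% and 28.1% of the 9-residue words of COX1 were seen in any read.

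**Figure D2:**
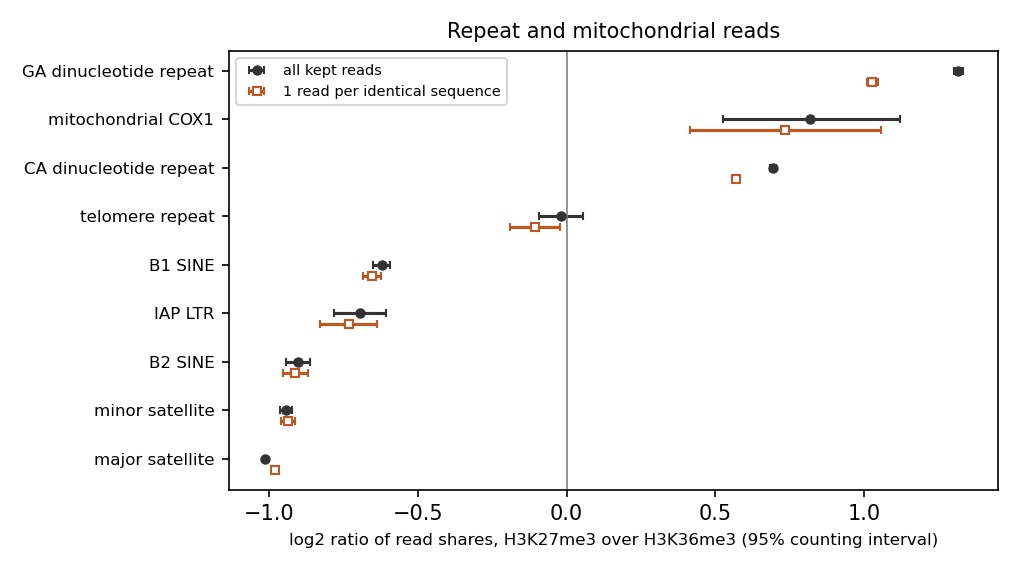
Log2 ratio of read shares, H3K27me3 over H3K36me3, for each repeat class and for mitochondrial COX1, over all kept reads (circles) and over 1 read per identical sequence (squares), with 95% counting intervals, 1 library per mark. Major satellite lies at −1.01 and GA repeats at 1.31 over all kept reads.

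Reads with at least 4 CpG dinucleotides, as in CpG islands, were slightly less frequent in H3K27me3, at 0.567% against 0.630% of distinct reads (log2 ratio −0.15, interval −0.16 to −0.14). The reverse dinucleotide GpC, counted as a control for base composition, also gave −0.15. At equal GC content the ratios were −0.26 (interval −0.27 to −0.25) for CpG and −0.23 for GpC.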

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

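Of the tests in this part, those on GC content and on the most frequent spelling of zinc finger reads were fixed before their results were seen, and the tests on shuffled peptides, on satellites and on GA repeats were chosen after the results were seen.

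Reads that hold the amplification primer stood out as signal outside the main measurement, at 2.25% of H3K27me3 reads and 1.73% of H3K36me3 reads. A second such signal came from 4 whole-read sequences present in both libraries, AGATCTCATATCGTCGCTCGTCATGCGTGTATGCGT, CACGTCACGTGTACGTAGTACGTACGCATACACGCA, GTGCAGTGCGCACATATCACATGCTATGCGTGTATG and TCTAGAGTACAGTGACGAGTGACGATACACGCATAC. Reads matching any of them made up 2.39% of H3K27me3 and 2.58% of H3K36me3 reads. Their shares were nearly equal between lanes, for example 0.565% and 0.559% for the first sequence.

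Zinc finger reads were far more frequent in H3K36me3, at a log2 ratio of −3.07. A GC difference between the libraries is argued against by the ratio at equal GC content, −3.06 (interval −3.30 to −2.82). An origin in 1 much amplified sequence is argued against by the ratio without the most frequent spelling of each family, −3.21 (interval −3.51 to −2.94). Chance matches to the peptides are argued against by their shuffled forms, which gave −0.22. What stays open is a difference between these libraries or lanes that is not due to the mark, which 1 library per mark leaves untested, and a biological candidate explanation is that zinc finger genes of LSK cells carry much H3K36me3.

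Major satellite reads were 2.02-fold higher in H3K36me3. Against other reads of the same GC content the log2 ratio was −1.07, which argues against GC content as the whole source. With 1 read per identical sequence it was −0.98, which argues only against identical PCR copies as the whole source. Preferential copying of satellite DNA during priming or PCR could still differ between the libraries, and a count of distinct reads cannot exclude it. An even rise of unspecific DNA of every kind in H3K36me3 is argued against by mitochondrial COX1 and L1 reads, which were on the H3K27me3 side with log2 ratios of 0.82 and 0.36, though only 47.2% and 28.1% of COX1 words were seen and the first panel's L1 interval, −0.003 to 0.51, included 0. A rise of unspecific nuclear repeat DNA stays open, since minor satellite, B2, IAP and B1 reads went with major satellite, at −0.94, −0.90, −0.69 and −0.62, while L1, CA and GA repeats, at 0.36, 0.69 and 1.31, and telomere repeats, at −0.02, did not. Telomere repeats leaned slightly to H3K36me3 at equal GC content, at −0.13 (interval −0.20 to −0.06). The L1 value is over distinct reads and the others over all kept reads. B1, B2 and IAP counts cover only copies that hold an exact consensus word. Mitochondrial DNA can vary with the preparation, antibody specificity was not tested, and the enrichment of satellites by the mark itself remains possible but without a replicate.

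GA repeat reads were higher in H3K27me3, at a log2 ratio of 1.31. The ratio was 1.22 against other reads of the same GC content, 1.03 with 1 read per identical sequence and 1.35 among reads with at least 30 good bases. GC content, identical PCR copies and the poorer base calls of the H3K36me3 lane are each argued against as the whole source. Preferential copying of simple repeats during priming or PCR could still differ between the libraries, and no biological explanation was tested.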

How the results depend on the processing

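No paired analysis was possible because the marks share replicate numbers in the labels but only replicate 2 of each was analysed here. The 42 alternatives fixed before the data were examined all need reads placed on a genome and were not run, and every alternative below was chosen after seeing the data. Zinc finger and machinery reads stayed higher in H3K36me3 under all 14 alternatives. Scaling to olfactory receptor reads and leaving satellite reads out of the totals could not have reversed them, since each lowers all family ratios alike. Without the scaling, the log2 ratios ran from −3.59 to −2.98 and from −2.81 to −1.24. Scaling to olfactory receptor reads lowers every log2 ratio alike by 1.51 and so tests no single family: it moved the groups to −4.58 for zinc fingers, −2.92 for machinery and −1.43 for developmental regulators, and reversed tissue-restricted families to −0.28, cadherins to −0.59 and L1 to −1.14. The first peptide panel gave −3.59 for zinc fingers and −2.81 for machinery, and subtraction of chance matches gave −3.33 and −2.24. In reads from the start and the end of the file, split evenly, tissue-restricted families stood at 1.59 (interval 1.07 to 2.14) and 0.99 (0.53 to 1.46) and developmental regulators at 0.32 (−0.41 to 1.06) and −0.49 (−1.34 to 0.33), with overlapping intervals and no test of the parts against each other. Major satellite stayed between −1.07 and −0.98: −0.98 with 1 read per identical sequence, −1.07 at equal GC content, −1.02 in bases 10 to 36, −1.02 in high-quality reads, −1.02 and −1.005 in the start and end of the file, and −1.0003 with up to 2 N allowed. The value at equal GC content sets satellite reads against other reads. It is therefore not on the scale of the ratios of shares, and its distance from them is not an effect of GC content alone. CpG-rich reads stood at −0.18 with identical reads kept, −0.26 at equal GC content, −0.19 in high-quality reads, −0.21 and −0.13 in the start and end of the file, −0.18 with up to 2 N and −0.18 without satellite reads. Under several alternatives the ratios of major satellite, CA and GA repeats moved beyond intervals that are narrow because of depth, and families with few reads are limited by depth. CpG content in bases 10 to 36 alone was not run.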

Other observations

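All searches in this part were made after the counts of families and repeats had been seen. A search of hexapeptides with at least 5 different residues, encoded by distinct reads outside satellites and simple repeats, tested 1869009 of them with at least 60 reads in both libraries together. Their median log2 ratio H3K27me3 over H3K36me3 was 0.02. The zinc finger linker hexapeptides TGEKPY and HTGEKP ranked 389 and 560 from the H3K36me3 end, with log2 ratios of −3.55 and −3.30. Many leading hexapeptides were translations of tandem repeats: repeat units found among strongly differing words encoded 31 of the 40 hexapeptides at the H3K27me3 end and 14 of the 40 at the H3K36me3 end.

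These repeat units came from a search of words of 21 bases. Of 47440 words with at least 200 reads in H3K27me3, 776 had a share at least 8-fold higher there than in H3K36me3, and 279 of 47695 words were as much higher in H3K36me3. Joined by overlap they formed 23 sequence families in each direction. These families were picked for their ratio, so their folds are on the high side. Those named below had the highest read counts summed over their words in each direction. An H3K27me3 family had a repeat unit of 62 bases, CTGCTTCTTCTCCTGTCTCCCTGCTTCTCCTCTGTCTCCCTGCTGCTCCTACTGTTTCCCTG, with 43896 reads against 1750 (log2 ratio 4.49). Over distinct reads it stood at 4.31. Another had a unit of 44 bases, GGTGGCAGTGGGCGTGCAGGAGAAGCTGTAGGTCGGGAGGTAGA, with 12847 reads against 442 (log2 ratio 4.70). In H3K36me3 a family had a unit of 19 bases, CACTCTCTGCCTTCAGATA, with 2040 reads against 29 in H3K27me3 (log2 ratio −6.30). A telomere-like family with the sequence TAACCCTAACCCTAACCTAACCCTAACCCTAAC had 2292 reads against 236 (log2 ratio −3.44), whereas the regular telomere repeat stood at −0.02. The positions of these arrays in the genome were not analysed here.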
